A study of Mus musculus with 15 samples.

How the data were processed

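Total RNA from 15 mouse mammary tumors was profiled on Affymetrix whole-transcript arrays, 1 array per tumor. Per the labels' protocols, biotin-labelled sense-strand cDNA was made from 100 ng of RNA per tumor with the Affymetrix WT Terminal Labeling Kit. The submitters' processing notes name Affymetrix Expression Console and Transcriptome Analysis Console. Their versions, the background correction and the normalization method are not given in the sources used here. The authors deposited a table of 41345 transcript clusters with a value for each tumor. The deposited values were taken as log2 intensities, because they ran from 1.06 to 13.9, above what a natural or decimal logarithm of scanner intensities can reach. They were not centred on genes. Median values per array lay between 5.54 and 5.73, so the arrays appear to have been normalized together by the authors. The highest median was that of the homozygous tumor called HOM 5 below, and the others reached at most 5.62. That array also had the highest lower quartile, 4.31 against 4.13 to 4.24. No scanner files were used here, so background correction could not be varied and no detection call was available. The number of arrays limits the precision of each value.

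Tumors were grouped by the genotype in the labels: Ctnnb1 wild type (WT), heterozygous floxed (HET) and homozygous floxed (HOM), with 5 tumors each. Replicate numbers follow accession order and pair nothing across genotypes. The labels do not say whether the tumors of a genotype came from separate mice, so p-values measure the spread between these tumors only. No batch or scan date was given.

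Transcript clusters were named through the platform annotation. Of the 41345 clusters, 25335 had a listed gene, 23521 had exactly 1 gene symbol, 1814 had several and 16010 were unnamed here. Among those with 1 symbol, 23328 were found by Entrez ID in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table served only for names and for which genes neighbour each other. Clusters with several symbols named no gene, so some well-known members of the gene lists were not tested. Of several clusters for a gene, the one with the highest mean over the 15 arrays was kept, leaving 22180 genes. A gene was tested when its value lay above the array's median of all clusters on at least 5 arrays, which left 14243 genes.

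The 3 genotypes were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values below are from this limma fit unless another test is named. Ctnnb1 was compared with a two-sided exact permutation test over the 252 assignments of 5 against 5 tumors, where the smallest possible p is 0.00794. For 44 fixed gene lists, the mean of the tested members was taken per tumor. The 43 lists with at least 5 tested members were compared with limma, adjusted over the lists. Camera with an estimated and with a preset correlation of 0.01 served as alternatives. A correlation of the HET and HOM effects was set beside 100 simulated sets of unchanged groups that shared their controls. Each simulated tumor was a random Gaussian combination of the residuals around the genotype means. An earlier version that permuted these residuals was discarded, because residuals of a genotype sum to 0 and 1 regrouping then gave a correlation of exactly 1 by construction.

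Genes were named by a fixed rule. It took 10 genes in every comparison (Ctnnb1, Jup, Cdh1, Erbb2, Grb7, Axin2, Lef1, Krt14, Krt8 and Vim), the genes past the threshold (up to 10 per direction, leaving out unnamed gene models), the 10 genes with the smallest p where fewer than 10 passed, and 3 members of each of the 4 lists with the smallest p. Genes named outside it are said to have been chosen after their values were seen. The gene test was checked on simulated data with the tested genes' means and SDs, in which 200 of 14243 genes were changed in HET. For HET against WT it recovered 54 of 100 genes changed by 1 on the log2 scale and 88 of 100 changed by 2, with 5 false calls among 147. Noise was drawn independently for each gene and tumor, so these rates leave out the shared variation of genes in real tumors.

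Further settings tried were no filter, a filter at the 75th percentile, renewed quantile normalization, median centring, the mean of all clusters of a gene, eBayes with trend and robust options, array weights, a fit of only the 2 genotypes compared, a linear model without moderation, leukocyte and fibroblast marker means as covariates, other thresholds and leaving out each tumor in turn. The grouping, tests, gene lists, naming rule and these settings were chosen before the data were examined. Leaving out WT 5 with HOM 5, and HET 1 with HET 3, was added after the data were seen.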

Results

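Gene expression was measured in mammary tumors of ErbB2KI mice, a model of Erbb2-driven breast cancer, with or without floxed Ctnnb1 alleles meant for deletion in the mammary epithelium. Ctnnb1 encodes beta-catenin, which joins cadherins to the cytoskeleton at adherens junctions and carries the canonical Wnt signal in the nucleus. Tumors were frozen at end burden and came from mice with wild-type (WT), heterozygous floxed (HET) or homozygous floxed (HOM) Ctnnb1, 5 tumors each. Values are log2 array values, given as mean ± SD (n = 5 tumors per genotype) unless stated. Across all pairs of tumors the correlation over 14243 tested genes had a median of 0.913. The closest pair was the tumors labelled WT 5 and HOM 1 at 0.977. Within genotypes the median correlation was 0.937 in WT, 0.863 in HET and 0.939 in HOM, so the HET tumors were the most diverse.

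Ctnnb1 itself, transcript cluster 17523257, was compared first as a check of the labels. Its level was 11.84 ± 0.39 in WT, 11.50 ± 0.19 in HET and 11.48 ± 0.33 in HOM. HET tumors thus had 79.1% of the WT level and HOM tumors 78.0%, and neither difference exceeded the spread between tumors (exact permutation p = 0.0952 and 0.143, both 0.214 after adjustment over the 3 comparisons). HOM and HET differed by -0.02 (95% interval -0.44 to 0.40, exact permutation p = 0.905), and by -0.15 without HOM 5 to 0.0606 without HOM 4. The tumor labelled WT 5 had a Ctnnb1 level of 11.22, within the range of the HOM tumors labelled 1 to 4 (11.15 to 11.58). In the tumor labelled HOM 5 the level was 12.01, within the WT range of 11.71 to 12.10 in the tumors labelled WT 1 to 4. These 2 values go against the labels, and each direction below that involves WT or HOM rests on labels that include these tumors. Without both, Ctnnb1 differed from WT by -0.49 in HET and -0.65 in HOM (exact permutation p = 0.00794 and 0.0286). That choice was made because of Ctnnb1 itself, so these p-values are no independent check. Where the cluster's probes lie relative to the deleted exons is not known here, and whole tumors also hold stromal cells, in which Ctnnb1 was not targeted.

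Jup encodes plakoglobin, a close relative of beta-catenin that serves both desmosomes and adherens junctions. Its level was 11.81 ± 0.69 in WT, 11.70 ± 1.14 in HET and 12.56 ± 0.78 in HOM, and no difference between genotypes passed the test (adjusted p = 0.944 for HET against WT, rounding to 1 for HOM against WT and 0.689 for HOM against HET). By tumor, Jup was between 12.79 and 12.98 in the tumors labelled HOM 1 to HOM 4 and 11.17 in the one labelled HOM 5. It was 12.98 in the tumor labelled WT 5 and between 11.31 and 11.82 in the other WT tumors. HET 3 was as high, at 12.98, and the other HET tumors lay between 9.94 and 12.25. HET 1 was the lowest, and without it HET differed from WT by 0.33 instead of -0.11 and HOM from HET by 0.42 instead of 0.86. Without WT 5 HET differed from WT by 0.18, and without HET 3 by -0.43.

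**Figure D1:**
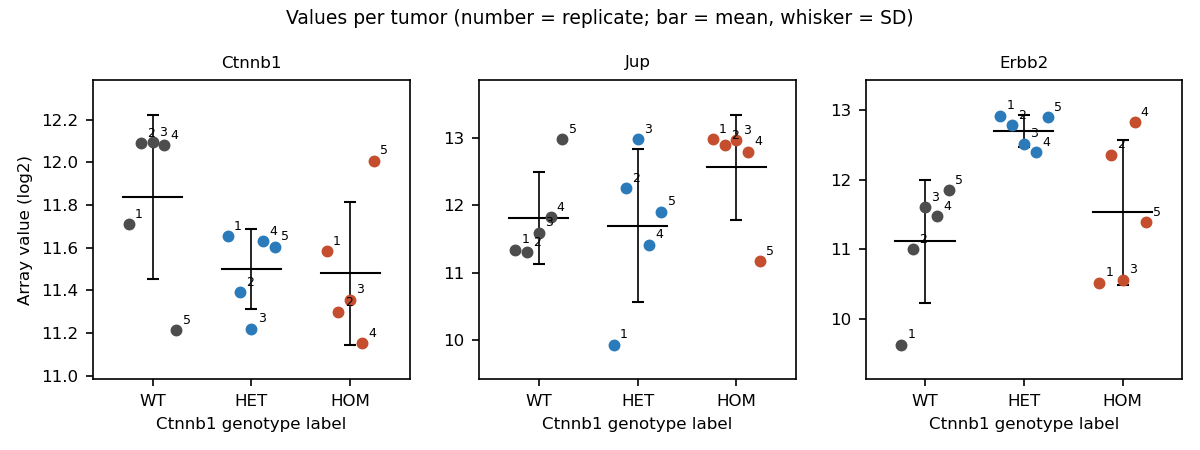
Array values (log2) of Ctnnb1, Jup and Erbb2 in each of 15 tumors by genotype label, with replicate numbers beside the points, the genotype mean as a bar and the SD as a whisker. The tumor labelled WT 5 is the lowest WT tumor for Ctnnb1 (11.22) and the highest for Jup (12.98). The tumor labelled HOM 5 is the highest HOM tumor for Ctnnb1 (12.01) and the lowest for Jup (11.17). Every HET tumor lies above every WT tumor for Erbb2.

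The comparison of HET with WT asked what differs in tumors with 1 floxed Ctnnb1 allele. Cdh19, which encodes a cadherin of Schwann and neural crest cells, fell from 7.70 ± 0.61 in WT to 4.18 ± 0.47 in HET (adjusted p = 0.00594, transcript cluster 17226127), and was lower in all 5 HET tumors than in every WT tumor. The HET values, 3.74 to 4.87, lay below the medians of their arrays (5.57 to 5.62) and around the lower quartiles (4.15 to 4.22). Signal over background was not analysed here, so the size of the decrease is uncertain. A530020G20Rik, an uncharacterised gene named after its values were seen, fell from 6.70 ± 0.26 to 5.54 ± 0.32 (adjusted p = 0.0307). Of the 14243 genes tested, 0 rose and these 2 fell in HET. At an unadjusted p under 0.05 there were 1905 genes, against 712 by chance on average. Genes vary together across tumors, so chance counts can lie far from this average. Their spread was not estimated, so 1905 cannot be read as an excess over chance. Among the other genes with the smallest p, none of which passed, Zfp275 was 2.85-fold higher in HET (7.63 ± 0.59 against 6.12 ± 0.33, adjusted p = 0.0945). Nrbp2 (8.40 ± 0.45 against 9.91 ± 0.51), Boc, a Hedgehog co-receptor (8.54 ± 0.60 against 10.48 ± 0.31), and Lgr4, a receptor for R-spondins that amplifies Wnt signalling (9.75 ± 0.58 against 11.18 ± 0.36), had lower HET means, with adjusted p of 0.136 or 0.137. Nsmf, Sardh, Rnf128, Ss18l2 and Arhgef26 likewise had lower means, by 1.70-fold to 2.93-fold (adjusted p from 0.137 to 0.170).

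Erbb2, the oncogene that drives the model, was 12.70 ± 0.23 in HET and 11.11 ± 0.88 in WT, a 3.01-fold higher mean. All 5 HET tumors lay above all 5 WT tumors (exact permutation p = 0.00794, the smallest that 5 against 5 tumors can give), but the difference did not pass adjustment over all genes (adjusted p = 0.224). Of the 15 tested members of the list of Erbb2 and its neighbours, Erbb2 included, 4 had a higher and 11 a lower mean in HET (adjusted p = 0.398 for the list). Pgap3, chosen after its values were seen, was 7.91 ± 0.54 in HET, a log2 difference of -3.09 from WT, and Stard3, chosen likewise, was 8.30 ± 0.42 in HET and 10.78 ± 2.16 in WT (adjusted p = 0.231 and 0.292). Grb7, an adaptor protein gene next to Erbb2, was 10.79 ± 1.98 and 11.75 ± 1.41 (adjusted p = 0.679), and its difference was -0.21 without HET 1 and -1.49 without WT 1 instead of -0.97. E-cadherin (Cdh1) had means of 11.07 ± 1.53 in HET and 11.74 ± 0.14 in WT, and the low HET mean came from HET 1 at 8.38. The Wnt targets Axin2 (6.95 ± 0.51 against 7.80 ± 1.73) and Lef1 (6.36 ± 0.61 against 7.37 ± 0.99) did not pass the test (adjusted p = 0.548 and 0.549). WT 1 carried the Axin2 difference with a value of 10.78, and without it the difference was -0.11 instead of -0.86. Keratin 14 (Krt14), keratin 8 (Krt8) and vimentin (Vim), markers of basal, luminal and mesenchymal cells, had adjusted p of 0.802, 0.597 and 0.717.

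Of the 43 gene lists, none shifted between HET and WT (limma, smallest adjusted p = 0.0565, with 5 lists at an unadjusted p under 0.05). That smallest p belonged to neutrophil markers, whose mean was 9.49 ± 1.20 in HET and 7.49 ± 0.42 in WT. Of its 14 tested members, 13 had a higher mean in HET, 0 passed over all genes, and 10 were higher and 1 lower adjusted over the list alone. The largest were Stfa2l1 (9.52 ± 1.52 against 5.18 ± 1.11), Retnlg (9.26 ± 1.61 against 5.38 ± 0.94) and the neutrophil collagenase Mmp8 (9.25 ± 1.97 against 6.40 ± 0.71). The exception was Lcn2 (log2 difference -0.62), which mammary epithelium also expresses. Adjusted p was 0.811 for this list with an estimated correlation. In the same tumors the pan-leukocyte mean was 9.17 ± 0.64 in HET and 8.58 ± 0.41 in WT, T and NK cell markers were 6.68 ± 0.97 and 6.68 ± 0.58, and fibroblast markers were 9.19 ± 1.74 and 8.76 ± 0.997 (adjusted p = 0.478, 0.999 and 0.855). The fibroblast difference was -0.0109 without WT 1, -0.14 without HET 4 and 1.08 without HET 5.

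Schwann cell and nerve markers, which did not include Cdh19, had a mean of 7.48 ± 0.36 in HET and 8.14 ± 0.47 in WT (adjusted p = 0.346). Of 8 tested members, 5 were lower and 3 higher, 0 passed over all genes, and 2 were lower and 1 higher adjusted over the list alone. The members with the smallest p were S100b (4.92 ± 0.80 against 7.66 ± 1.28), the neural crest transcription factor Sox10 (8.72 ± 1.81 against 10.89 ± 0.48) and Ngfr (6.94 ± 0.22 against 6.37 ± 0.40). Sox10 lay between 6.92 and 8.14 in HET 1, HET 2 and HET 4 and was 10.66 in HET 3 and 10.61 in HET 5. Cdh19 did not follow this split and was 4.41 in HET 3 and 3.74 in HET 5. Kit, a luminal progenitor marker, did, with 10.80 in HET 3, 10.19 in HET 5 and 8.51 to 9.18 in the others. The cells that gave the Sox10 signal were not identified, so the Schwann label of this list need not apply to it. Wnt/beta-catenin target genes had a mean of 7.97 ± 0.22 in HET and 8.55 ± 0.53 in WT (adjusted p = 0.346), with 15 of 20 members lower and 0 past the threshold, adjusted over the list alone or over all genes. WT 1 had the highest mean of this list, 9.27. The other WT tumors lay between 7.94 and 8.84 and the HET tumors between 7.85 and 8.37. Rnf43 and Znrf3, which encode ubiquitin ligases that remove Wnt receptors, were 8.01 ± 0.98 against 9.60 ± 0.78 and 7.95 ± 0.45 against 8.92 ± 0.91. Tnfrsf19 was 7.73 ± 1.62 against 9.42 ± 0.86. In HET 3 and HET 5 Tnfrsf19 was 9.70 and 9.31, near its WT mean, and 6.53 to 6.59 in the other HET tumors. Rnf43 was 9.34 in HET 3 and 6.88 to 8.54 in the other HET tumors. ErbB receptors and ligands had a mean of 8.88 ± 0.45 in HET and 8.22 ± 0.58 in WT (adjusted p = 0.346), with 8 of 10 members higher, 0 past the threshold over all genes and 3 adjusted over the list alone. These 3 were Erbb2, the ligand epiregulin (Ereg, 8.82 ± 2.03 against 6.49 ± 0.42) and Nrg4 (6.10 ± 0.14 against 5.82 ± 0.08). Ereg was 8.76 to 11.40 in HET 1, HET 2 and HET 4. In HET 3 and HET 5 it was 7.19 and 6.54, near the WT values of 6.04 to 7.19. Without WT 1 the ErbB list differed by 0.42 instead of 0.66. With an estimated correlation each of these 3 lists also had an adjusted p of 0.811. Junction and epithelial genes did not pass either. Tight junction genes were 9.02 ± 1.17 in HET and 9.72 ± 0.28 in WT (14 of 15 members lower) and epithelial markers 9.49 ± 1.31 and 10.11 ± 0.35 (18 of 20 lower), both with an adjusted p of 0.572. Both differences rested on HET 1, without which they were -0.25 instead of -0.70 and -0.0930 instead of -0.62. Adherens junction and desmosome genes had an adjusted p of 0.897, and leaving out 1 tumor could turn their direction. Adjusted over the list alone, 1 desmosome gene was higher and 1 lower, and 0 adherens junction genes passed. The difference ranged from -0.0621 without WT 1 to 0.14 without WT 4 for adherens junction genes, and from -0.15 without HET 2 to 0.65 without HET 1 for desmosome genes.

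Some HET tumors stood apart in cell type markers. B and plasma cell markers had a mean of 9.65 in HET 1 and 6.09 to 6.54 in the other HET tumors, and epithelial markers were 7.37 in HET 1. Skeletal muscle markers were 10.61 in HET 3 and 5.89 to 6.54 in the other HET tumors. Without HET 3 the comparison of HET with WT called 48 genes (16 higher, 32 lower in HET) and the neutrophil list, and without HET 5 it called 18 genes and the same list. Without HET 1 and HET 3, a choice made after seeing the data, it called 10 genes. With 1 tumor left out, A530020G20Rik stayed past the threshold only without WT 5, HET 3 or HET 5. Its adjusted p was 0.0566 with renewed quantile normalization, 0.0592 with array weights, 0.412 with only the 2 genotypes compared and 0.0700 without moderation. Cdh19 lost its call with array weights and with the leukocyte and fibroblast covariates (adjusted p = 0.0592 and 0.0902, the latter the highest of a range that starts at 0.00243 over all alternatives that tested it). Its difference went from -3.52 (standard error 0.401) to -3.34 (0.469) and -3.28 (0.472), so the call ended with a smaller difference and, in proportion, a larger change of its standard error.

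**Figure D2:**
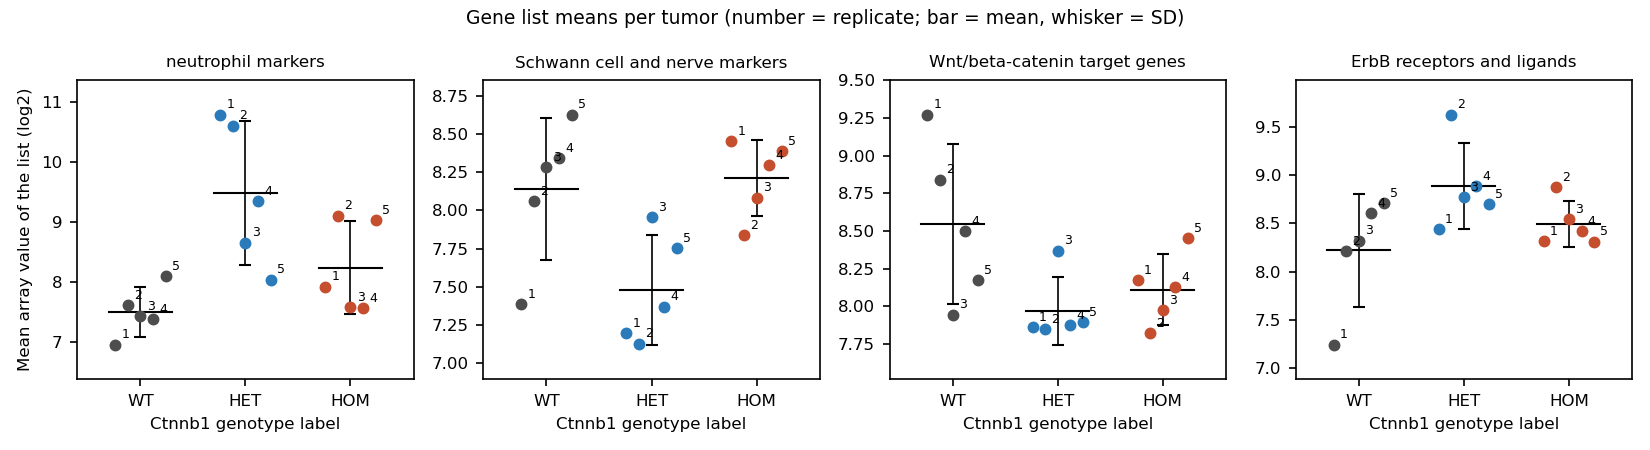
Mean array value (log2) per tumor of 4 gene lists by genotype label, with replicate numbers beside the points, the genotype mean as a bar and the SD as a whisker. Neutrophil markers had the largest separation of HET from WT (9.49 ± 1.20 against 7.49 ± 0.42), with HET 1 and HET 2 the highest, and no list passed the threshold.

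The comparison of HOM with WT asked what differs in tumors with 2 floxed alleles. Deletion of these alleles was not shown by the Ctnnb1 values, so the comparison is of genotype labels. No gene passed the limma test (0 higher, 0 lower), and none passed in the linear model without moderation. At an unadjusted p under 0.05 there were 242 genes, fewer than the 712 that chance gives on average, and the spread of such counts was not estimated. The 10 genes with the smallest p all had an adjusted p that rounded to 1, so none is a call. They included Cdh19 (6.04 ± 0.89 in HOM against 7.70 ± 0.61 in WT), the potassium channel gene Kcnj15 (6.68 ± 0.24 against 7.67 ± 0.21), the calcium sensor Stim1 (7.84 ± 0.16 against 8.34 ± 0.20), the heparan sulfate sulfotransferase Hs3st3b1 (7.09 ± 0.29 against 8.48 ± 1.16), Dhtkd1 (6.41 ± 0.25 against 6.96 ± 0.17) and Ivd (8.26 ± 0.20 against 8.91 ± 0.46). Abca2, Trpt1 and Bcl2l2 had lower HOM means by 1.27-fold to 1.55-fold, and Eif4a3 a mean 1.27-fold higher. Erbb2 was 11.53 ± 1.04 in HOM and 11.11 ± 0.88 in WT, a difference of 0.42 that was 0.0503 without WT 1, 0.21 without HOM 2, 0.0968 without HOM 4, 0.67 without HOM 1 and 0.66 without HOM 3. Krt14 differed by 1.62 (12.17 ± 0.70 against 10.54 ± 1.66). Cdh1, Krt8 and Vim had differences of either sign with 1 tumor left out, 0.0347 for Cdh1 without HOM 5, and -0.0517 for Krt8 and -0.16 for Vim without WT 1, instead of -0.0742, 0.0594 and 0.14. Axin2 (7.31 ± 0.19 against 7.80 ± 1.73), Lef1 (6.99 ± 1.81 against 7.37 ± 0.99) and Grb7 (10.96 ± 1.60 against 11.75 ± 1.41) did not pass either. Axin2 differed by 0.25 without WT 1 and -0.82 without WT 3 instead of -0.49. Lef1 ranged from -1.15 without HOM 5 to -0.0366 without HOM 3, and Grb7 from -1.31 without WT 1 to -0.16 without HOM 5.

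None of the 43 lists shifted between HOM and WT (limma, 0 lists at an unadjusted p under 0.05). The 4 lists with the smallest p each had an adjusted p of 0.968, and 0.829 with an estimated correlation. Wnt/beta-catenin target genes had the smallest p, with means of 8.11 ± 0.24 in HOM and 8.55 ± 0.53 in WT, 18 of 20 members lower and 0 past the threshold adjusted over the list alone. WT 1 had the highest mean (9.27), and without it the difference was -0.25 instead of -0.44. Within it, Ascl2 was 5.74 ± 0.17 against 6.32 ± 0.62 and Nkd1 6.38 ± 0.39 against 7.82 ± 1.88, with a WT mean raised by WT 1 at 10.72. Znrf3 was 8.09 ± 0.28 against 8.92 ± 0.91. Without WT 1 these 3 genes differed by -0.37, -0.72 and -0.53. Adipocyte markers (7.43 ± 0.77 against 6.87 ± 0.14) had 13 of 14 members higher, among them Adipoq, Lep and Retn with log2 differences of 0.80, 0.85 and 0.88. HOM 4 lay at 8.66, and without it the list differed by 0.25 instead of 0.56 and these genes by 0.44, 0.36 and 0.55. Neutrophil markers (8.24 ± 0.77 against 7.49 ± 0.42) had 13 of 14 members higher, with Stfa2l1 at 7.10 ± 1.93 against 5.18 ± 1.11, Retnlg at 7.00 ± 1.34 against 5.38 ± 0.94 and Il1b at 9.63 ± 0.97 against 8.52 ± 1.45, a difference that was 0.52 without WT 1. Interferon response genes (8.05 ± 0.97 against 8.82 ± 0.94) had 16 of 17 members lower, with Irf7, Usp18 and Ifit1 at fold differences of 2.32, 2.51 and 2.35. That list differed by -0.78, by -0.43 without WT 3 and by -0.48 without HOM 1, and without HOM 1 these genes differed by -0.79, -0.69 and -0.70 on the log2 scale. None of these lists had a member past the threshold adjusted over the list alone. Adherens junction, desmosome and tight junction genes had adjusted p of 0.968, 0.968 and 0.988. With 1 tumor left out, adherens junction genes ranged from -0.0844 (WT 1) to 0.11 (WT 4), desmosome genes from 0.0439 (WT 1) to 0.33 (HOM 5) and tight junction genes from -0.11 (HOM 3) to 0.22 (HOM 5).

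Without the tumors labelled WT 5 and HOM 5, a choice made after seeing their Ctnnb1 values, 4 genes were higher in HOM than in WT and 0 lower. They were Klhl11 (10.62 against 8.01, adjusted p = 0.000565), the pseudogene Eif1-ps3 (11.11 against 9.77, adjusted p = 0.0110), Klhl10 (6.39 against 5.45, adjusted p = 0.0155) and Nt5c3b (10.68 against 8.81, adjusted p = 0.0489). Klhl11, Klhl10 and Nt5c3b lie beside Jup in the GRCm38.p6 gene table, and Eif1-ps3 lies on another chromosome. The value of this pseudogene is uncertain, because its probes can also read near-identical copies. Where such copies lie was not examined here, so its call cannot be counted as separate from the genes beside Jup. Because these tumors were left out for what was measured in them, these counts are not independent of the values that put the labels in doubt. With all tumors and after their values were seen, Klhl11 had means of 10.01 ± 1.40 in HOM and 8.51 ± 1.15 in WT, Nt5c3b 10.26 ± 0.96 and 9.18 ± 0.92, P3h4 10.99 ± 1.18 and 9.36 ± 1.33, Cnp 10.62 ± 0.83 and 9.37 ± 1.01, and Acly, which encodes ATP citrate lyase, 12.56 ± 1.22 and 11.55 ± 1.17, all with an adjusted p that rounded to 1. Without HOM 5 alone Acly differed by 1.54 instead of 1.01.

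**Figure D3:**
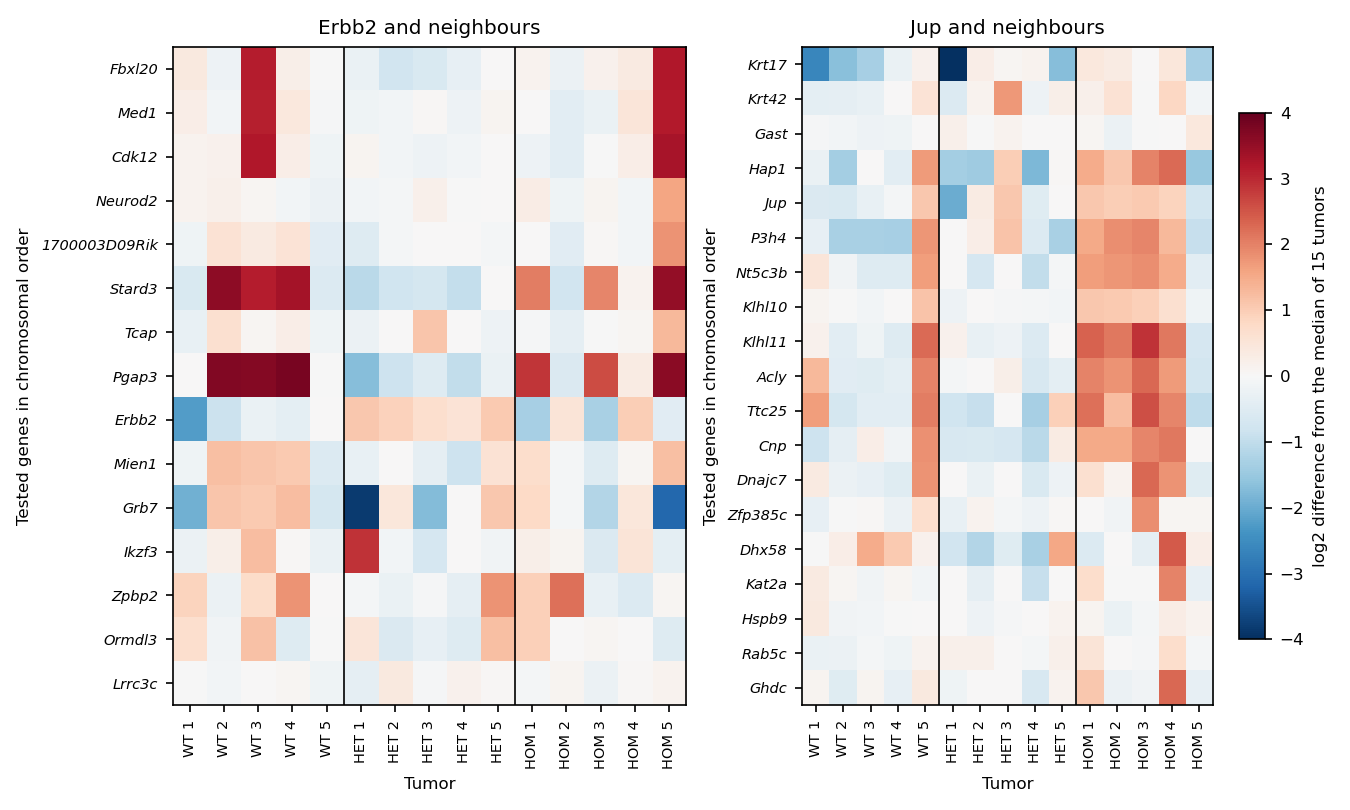
Difference in log2 value from the median of the 15 tumors for tested genes in chromosomal order around Erbb2 (left) and Jup (right), 1 column per tumor and with lines between genotypes. Klhl11 lies 2.11 to 2.88 above the median in the tumors labelled HOM 1 to HOM 4 and 2.27 above it in the tumor labelled WT 5, and Pgap3 lies 3.68 to 3.81 above it in WT 2, WT 3 and WT 4 and is also high in HOM 1, HOM 3 and HOM 5, by at most 3.60.

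The comparison of HOM with HET asked what differs between tumors with 2 floxed alleles and tumors with 1. No gene passed the limma test (0 higher, 0 lower), with 1129 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.448; the linear model without moderation also called 0. That p belonged to Ppan, a ribosome biogenesis factor, at 10.52 ± 0.19 in HOM, a log2 difference of 1.02 from HET. The other genes with the smallest p had an adjusted p of 0.587. Nsmf (8.18 ± 0.16 against 7.48 ± 0.14), Sardh (8.62 ± 0.25 against 7.25 ± 0.60), Boc (10.17 ± 0.82 against 8.54 ± 0.60), Nrbp2 (9.55 ± 0.28 against 8.40 ± 0.45) and Cdh19 (6.04 ± 0.89 against 4.18 ± 0.47) had higher HOM means, as did Trip6 and Marchf3. Dpy19l3 (6.76 ± 0.23 against 8.26 ± 0.81) and Hccs (9.62 ± 0.11 against 10.22 ± 0.29) had lower ones. Erbb2 was 11.53 ± 1.04 in HOM and 12.70 ± 0.23 in HET (adjusted p = 0.587). Differences were 0.60 for Cdh1, 0.18 for Grb7, 0.37 for Axin2, 0.63 for Lef1, 0.96 for Krt14, 0.27 for Krt8 and -0.17 for Vim, with adjusted p between 0.690 and 0.973 for these 7 genes. Without HET 1 the differences were -0.0761 for Cdh1, -0.58 for Grb7 and -0.0571 for Krt14 and -0.00991 for Vim, and without HOM 5 they were 0.81 for Grb7, -0.14 for Lef1 and -0.31 for Vim. Axin2 differed by 0.58 without HET 3 and Krt14 by 1.51 without HET 2.

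No list shifted between HOM and HET (limma, 3 lists at an unadjusted p under 0.05), and each list had an adjusted p of 0.951 with an estimated correlation. Schwann cell and nerve markers were 8.21 ± 0.25 in HOM and 7.48 ± 0.36 in HET (adjusted p = 0.413), with 6 of 8 members higher and 2 past the threshold adjusted over the list alone, Cnp (10.62 ± 0.83 against 8.67 ± 0.52) and Sox10 (10.77 ± 0.21 against 8.72 ± 1.81). Cnp is also one of the genes beside Jup. S100b was 6.19 ± 1.37 against 4.92 ± 0.80, a difference of 0.73 without HOM 5 instead of 1.27. Neutrophil markers were 8.24 ± 0.77 and 9.49 ± 1.20 (adjusted p = 0.556), with 13 of 14 members lower in HOM and 0 past the threshold adjusted over the list alone. Mmp8, Retnlg and Stfa2l1 differed by -2.36, -2.25 and -2.42. In the same tumors pan-leukocyte markers lay between 8.16 and 9.23 in HOM and between 8.24 and 9.92 in HET. Luminal progenitor markers were 10.02 ± 0.65 and 9.20 ± 0.77 (adjusted p = 0.606), with 10 of 12 members higher and 5 past the threshold adjusted over the list alone, including Kit (10.77 ± 0.70 against 9.54 ± 0.93), Mfge8 (12.97 ± 0.17 against 12.16 ± 0.54) and Lbp (11.62 ± 0.41 against 10.82 ± 0.63). Milk and alveolar secretion genes were 10.53 ± 0.88 and 9.49 ± 1.08 (adjusted p = 0.737), with 14 of 14 members higher and 0 past the threshold adjusted over the list alone, among them alpha-lactalbumin (Lalba, 11.64 ± 0.43 against 8.66 ± 2.32) and kappa-casein (Csn3, 12.40 ± 0.35 against 11.42 ± 0.997). Epithelial markers were 10.20 ± 0.38 and 9.49 ± 1.31 in the same tumors. Without HET 5 the milk genes differed by 0.67 instead of 1.04, and without HET 1 the epithelial markers by 0.18 instead of 0.71. Without the tumors labelled WT 5 and HOM 5, a choice made after their values were seen, 6 genes were higher in HOM than in HET. They were Klhl11, Klhl10, Nt5c3b and Cnp, which lie beside Jup, with the pseudogene Eif1-ps3 and Snord61. This count is not independent of the values that put the labels in doubt. Leaving out HET 3 gave 1 gene and leaving out HET 5 gave 3.

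A further test set HET against the mean of WT and HOM. Cdh19 was the only gene past the threshold (0 higher, 1 lower, adjusted p = 0.0262), and 8 genes passed an adjusted p of 0.10. Without HET 3 the count was 119 (47 higher, 72 lower), and without HET 5 it was 62. It was 0 without WT 1, WT 3, WT 4, WT 5, HET 1, HET 4, HOM 1 or HOM 2. Without HET 1 and HET 3 it was 8.

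The effects of HET and of HOM, each against WT, correlated over genes with r = 0.545 and a covariance of 0.0642. Genes are not independent replicates, and both effects share the WT tumors. Simulated unchanged groups that shared their controls gave r = 0.489 ± 0.261 (mean ± SD of 100 simulations) and a covariance of 0.0544 ± 0.0420. The observed covariance exceeded the simulated mean by 0.00979, less than the simulations' SD. With the WT tumors split into 2 and 3, so that the effects shared no control, r averaged 0.0794 over 20 splits, with a range of -0.0547 to 0.198.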

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

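Of the tests in this part, the exchange of labels and the splits of the tumors were planned before their results were seen, and the tests on stroma, on the neighbours of Jup and on Erbb2 were chosen only after. Of 246 groups of 5 tumors, 22 held a tumor far from the other 4, where chance gives about 1 in 20, or 12, and 8 of the 22 lay in the tumor labelled HOM 5. These groups are not independent, since the genes beside Jup move together and were in part chosen after their values were seen. With only the genes and lists named by the rule fixed in advance, 13 of 204 groups held such a tumor, against 10 by chance, and 4 of the 13 lay in HOM 5.

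The tumor labelled WT 5 had the Ctnnb1 and Jup levels of HOM 1 to HOM 4, and the tumor labelled HOM 5 had Ctnnb1 at 12.01 and Jup at 11.17. Of the Ctnnb1 and Jup values of WT 5 and HOM 5, only Jup in HOM 5 was among the far tumors counted above. An exchange of these 2 labels could not be tested through the genes beside Ctnnb1, because 0 of 40 neighbours followed the number of floxed alleles in the other 13 tumors (smallest adjusted p = 0.110). More stroma in HOM 5 may raise its Ctnnb1: its fibroblast mean was 10.12 against at most 9.55 in the other HOM tumors. Its pan-leukocyte mean, 8.92, lay below the highest of the other HOM tumors, 9.23. However, a fit on fibroblast and pan-leukocyte means left a difference of 0.65 from 0.66, with a residual SD of 0.36. Both explanations and a tumor that escaped deletion stay open, and escape from deletion was not tested. More stroma in HOM 5 or its escape from deletion would leave the Ctnnb1 and Jup levels of WT 5 unexplained. The array of HOM 5 also had the highest median, 5.73 against at most 5.62, and what this means for its values was not tested.

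Jup and its neighbours were high together in HOM 1 to HOM 4 and WT 5, while HOM 5 was low for Jup (11.17), Acly (10.42), Cnp (9.21), Klhl11 (7.57), Nt5c3b (8.56) and P3h4 (8.93), and WT 5 was high for Klhl11 (10.52 against 7.73 to 8.42 in the other WT tumors). HET 3 was as high for Jup (12.98), with P3h4 at 10.98 and Hap1 at 9.22, but had Klhl11 at 8.04, Nt5c3b at 8.98 and Acly at 11.38, so a high Jup did not always come with these neighbours. The 10 nearest genes had a mean of 9.73 to 9.98 in HOM 1 to HOM 4 and WT 5 and at most 9.28 in the other 10 tumors (difference of means 1.56, SD of the other 10 0.474). High values in these 5 were thus not limited to Jup. However, these tumors and genes were picked after being seen high together, and the measure was chosen with all values known. The difference therefore cannot test a change of Jup alone. The SD of the mean of the 10 nearest genes over all tumors, 0.855, lay at percentile 99.7 of 14010 windows, and its variance ratio at 99.3. For each side of Jup alone, the SD lay at percentile 99.3 with the keratins, which vary with squamous differentiation, and 99.5 from P3h4 to Acly. The variance ratio of these sides lay at 90.7 and 99.96. However, these genes were tested because they had been seen high with Jup. A gain of the segment, for which DNA copy number was not analysed here, and joint regulation of these genes both stay open.

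Erbb2 was higher in HET than in WT by 1.59, without passing adjustment over all genes. The mean of its neighbours Stard3, Pgap3, Mien1 and Grb7 was not higher in HET and differed by -1.81 (standard error 0.788, exact permutation p = 0.0794). The WT tumors were split, with Pgap3 at 12.45 to 12.57 in WT 2, WT 3 and WT 4 and at 8.77 and 8.74 in WT 1 and WT 5. Because the difference depends on this split, it cannot decide on a gain of the whole segment in HET. A gain that spares the neighbours also stays open. With leukocyte and fibroblast means as covariates the Erbb2 difference was 1.11 (standard error 0.510), so a part played by cell shares may remain and cannot be told apart from genotype. HOM, with 2 floxed alleles, lay at 11.53, a difference of -1.17 from HET (exact permutation p = 0.0476, adjusted p over all genes 0.587). The HOM tumors were split. HOM 2 and HOM 4 lay at 12.36 and 12.83, near the HET values of 12.39 to 12.92, and HOM 1, HOM 3 and HOM 5 at 10.52 to 11.39. With this split and the doubt over HOM 5, a dependence on the number of alleles cannot be judged.

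Other tumors far from the rest of their genotype are given as values. HET 1 had B and plasma cell markers at 9.65 (others 6.09 to 6.54) and Cdh1 at 8.38 (others 11.41 to 12.16). HET 2 had Ngfr at 6.56 (others 6.95 to 7.09). HET 3 had Wnt/beta-catenin target genes at 8.37 (others 7.85 to 7.89) and skeletal muscle markers at 10.61 (others 5.89 to 6.54). HET 5 had interferon response genes at 9.31 (others 7.28 to 7.80), with Ifit1 at 10.34 and Usp18 at 11.41. HOM 4 had Lep at 8.06 (others 5.43 to 6.05). HOM 5 also had Lef1 at 10.08 (others 5.63 to 6.78) and milk and alveolar secretion genes at 9.02 (others 10.67 to 11.31). WT 1 had Lef1 at 5.64 (others 7.49 to 8.11) and fibroblast markers at 6.99 (others 9.05 to 9.37). WT 3 had B and plasma cell markers at 7.50 (others 6.41 to 6.72). WT 4 had Sox10 at 11.73 (others 10.60 to 10.87).

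Chance could not be excluded for the 2 counts above 0. For HET against WT, 7 of 100 splits of the tumors, the labels' own among them, gave at least the 2 genes of the labels, and the highest other split gave 20. For HET against the mean of WT and HOM, 6 of 100, counted likewise, gave at least 1 gene, with 4 the highest other. For HOM against WT and HOM against HET the labels gave 0, which all 100 splits reach by definition, so the splits say nothing of chance there, and 11 and 39 were the highest others. In the order of these 4 comparisons, 14, 5, 4 and 6 of the other splits called any gene. The few high counts point to a structure in those splits of the tumors, and what it is was not tested. The split that gave 11 was the one in which the tumors labelled WT 5 and HOM 5 traded places. That split also separates the tumors in which the genes beside Jup had been seen high from WT 1 to WT 4 and HOM 5. The count is therefore not independent of that pattern and is no separate evidence for an exchange of labels.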

How the results depend on the processing

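The 2 settings that leave out a pair of tumors were chosen only after the data were seen, and all other settings here were planned. The number of genes changed between HET and WT (2) became 0 with the stricter filter, which removed Cdh19, and 0 with array weights. It became 1 with renewed quantile normalization, with only the 2 genotypes compared and without moderation, where Cdh19 stayed. It also became 1 with leukocyte and fibroblast covariates, where A530020G20Rik stayed. For HET against the mean of WT and HOM, 1 gene became 0 with the stricter filter, array weights, no moderation and covariates, and 8 at an adjusted p under 0.10. Lists shifted between HET and WT (0) became 1 with the stricter filter, at an adjusted p under 0.10 and with the median of the list members. Camera with a preset correlation called 18 lists for HET against WT, 16 for HOM against WT and 11 for HOM against HET, and with an estimated correlation 0 in each. Apart from the filter, the cause was not tested.

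Without the tumors labelled WT 5 and HOM 5, the counts were 4 for HOM against WT, 6 for HOM against HET and 2 for HET against the mean. Ctnnb1 then differed by -0.49 for HET and -0.65 for HOM against WT, with exact permutation p of 0.00794 and 0.0286, the smallest that these numbers of tumors give, while the limma adjusted p of 0.200 and 0.433 did not pass. The tumors were left out because of Ctnnb1 itself. Jup turned to 0.18 for HET against WT, Cdh1 to 0.0592 for HOM against WT and Lef1 to -0.14 for HOM against HET. Without HET 1 and HET 3, the counts were 10 for HET against WT, 1 for HOM against HET and 8 for HET against the mean. Then Jup turned to 0.0455, Cdh1 to 0.00996 and Grb7 to 0.35 for HET against WT, and Cdh1 to -0.0842, Grb7 to -1.14 and Krt14 to -0.00838 for HOM against HET.

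With array weights Vim turned to -0.00625 for HOM against WT. With covariates, Jup turned to 0.47 and Vim to -0.00298 for HET against WT, Cdh1 to 0.0257 and Vim to -0.00331 for HOM against WT, and Ctnnb1 to 0.0407, Axin2 to -0.0752 and Krt14 to -0.10 for HOM against HET. None of these values had passed a test, and the cause was not tested.

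With each tumor left out in turn, genes changed ranged from 1 to 48 for HET against WT (48 without HET 3, 18 without HET 5), 0 to 3 for HOM against HET (3 without HET 5, 1 without HET 3) and 0 to 119 for HET against the mean (119 without HET 3, 62 without HET 5). For HOM against WT the count stayed 0. Lists shifted between HET and WT ranged from 0 to 1 (1 without HET 3 or HET 5). Ctnnb1 ranged from -0.49 to -0.27 for HET against WT and from -0.51 to -0.28 for HOM against WT, with exact permutation p of 0.00794 and 0.0317 without WT 5, and from -0.15 to 0.0606 for HOM against HET. For HET against WT, Jup ranged from -0.43 to 0.33 and Cdh1 from -0.94 to 0.00189. For HOM against WT, Cdh1 ranged from -0.14 to 0.0347, Axin2 from -0.82 to 0.25, Krt8 from -0.0517 to 0.16 and Vim from -0.16 to 0.31. For HOM against HET, Cdh1 ranged from -0.0761 to 0.87, Grb7 from -0.58 to 0.81, Lef1 from -0.14 to 0.97 and Krt14 from -0.0571 to 1.51. The correlation of the HET and HOM effects ranged from 0.394 to 0.634. Signal over background was not analysed here.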

Other observations

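No test was added in this part, and the lists, genes and tumors named were picked only after their values were seen. Camera with a preset correlation called 18 lists for HET against WT and 16 for HOM against WT, where limma on list means and camera with an estimated correlation called 0. The 3 lists below are examples. MHC class I and antigen processing genes had means of 9.66 ± 0.58 in WT, 9.19 ± 0.56 in HET and 9.27 ± 0.56 in HOM, with 12 of 12 members lower than in WT in each (limma adjusted p = 0.572 and 0.968, camera 0.0341 and 0.00159 with a preset and 0.811 and 0.829 with an estimated correlation). Without WT 3 the differences were -0.24 and -0.16 instead of -0.48 and -0.39, and without HET 5 and HOM 4 they were -0.72 and -0.63. Adjusted over the list alone, 0 members passed in either. Oxidative phosphorylation genes were 9.74 ± 0.17 in HET and 9.96 ± 0.22 in WT, with 19 of 19 members lower and 0 past the threshold adjusted over the list alone (adjusted p = 0.572, camera 0.00355 with a preset and 0.811 with an estimated correlation). The difference of -0.22 was -0.13 without WT 1. In HOM 15 of 19 members were lower than in WT, the difference of -0.0716 ranged from -0.13 without WT 4 to 0.0194 without WT 1, and no test was passed (limma adjusted p = 0.968, camera 0.173 with a preset correlation). Chemokines and cytokines were 8.57 ± 0.75 in HET and 7.69 ± 0.52 in WT, with 19 of 22 members higher and 2 past the threshold adjusted over the list alone (adjusted p = 0.346, camera 4.52e-05 with a preset and 0.811 with an estimated correlation).

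Single tumors differed widely within a genotype. Keratinisation and squamous genes had means of 10.86 in HET 2, 10.32 in HOM 2 and 9.79 in HET 3, against 6.15 in HET 1 and 6.20 in HET 5 (adjusted p = 0.741 for HET against WT). WT 1 had the highest mean of the Wnt/beta-catenin target genes, 9.27, against 7.82 to 8.84 in the other tumors. Members that feed back on Wnt signalling, picked because they were high there, were Axin2 (10.78), Nkd1 (10.72), Rnf43 (10.89) and Znrf3 (10.13). Lef1, of the same list, was 5.64 in WT 1, and the remaining members were not tallied for this tumor. Fibroblast markers were 11.46 in HET 4 and 6.62 in HET 5. Pgap3, beside Erbb2, was 11.37 to 12.57 in WT 2, WT 3, WT 4, HOM 1, HOM 3 and HOM 5, 8.19 to 9.08 in WT 1, WT 5, HOM 2 and HOM 4, and at most 8.49 in the HET tumors.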
